A study of Homo sapiens with 2 samples.

How the data were processed

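RNA-seq was deposited for 2 cultures of HCT116, a human colon cancer cell line. Per the labels' protocols, 1 culture was transfected with a non-specific siRNA (siControl) and the other with an siRNA against KAT7 (siKAT7), with a lipid reagent. RNA was extracted with TRIzol and libraries were built from total RNA. Whether poly(A) RNA was selected or rRNA was removed is not given in the sources used here, and neither is the strand setting. There was 1 library per group, so no difference between the groups has a replicate check.

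The deposited count table holds expected counts per gene, which are estimated read counts that need not be whole numbers. RSEM 1.3.3 and GRCh38.p13 are named per the submitters' processing notes. The aligner and the annotation release are not given in the sources used here. Of the values in named genes, 11.8% were not whole numbers, because RSEM divides reads that fit several gene models. The table has 60954 rows, of which 60623 carry a gene name. The other 331 rows are unnamed assembled loci, which hold 1.11% of all counts in siControl and 1.67% in siKAT7. Those rows stayed out of the library sizes and comparisons. The table repeats both count columns under the same names with 0 differing cells, so each library was used once in place of the sum that had been planned for separate runs.

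A deposited table of the authors' own comparison gives, per gene, a fold (the ratio of siKAT7 to siControl), its log2, a p-value and an adjusted p-value. The tool behind them is not given in the sources used here. Of 10163 genes with at least 200 counts summed over both libraries and counts in each, 99.98% had a log2 fold in the authors' deposited table within 0.001 of the ratio of total-count-scaled counts. The authors' mark of significance coincided with an absolute log2 fold of at least 1 and an adjusted p under 0.001, with 0 exceptions. A p-value between 2 libraries compares those libraries and not the conditions.

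Expected counts of the named genes summed to 23450326 in siControl and 23533134 in siKAT7. They were rounded to whole numbers and scaled by the TMM factors of edgeR 4.0.16 (1.04 for siControl and 0.964 for siKAT7) in R 4.3.3. Each gene's log2 ratio, siKAT7 over siControl, was taken from CPM (counts scaled to the library size) with a prior count of 0.5. Its exact Clopper-Pearson 95% interval came from the split of the gene's counts between the libraries. These intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules and the spread between cultures is unknown. Genes with a mean of at least 1 CPM were kept. A gene counted as higher or lower at a log2 ratio of at least 1 in size with an interval that excluded 0.

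Gene lists were fixed before the data were examined, 38 in all, and their symbols were matched by Ensembl identifier. Of 790 symbols, 788 matched. Each list with at least 5 measured members was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size, matched on 20 bins of mean expression. A list was taken to stand apart when it lay outside the central 95% of the random lists. List members at least 1.5-fold higher or lower with an interval that excluded 0 were counted. The percentiles describe these 2 libraries and are no test of the treatment. Types and coordinates came from GENCODE 29 on GRCh38, where 58516 of the 60623 gene identifiers were found, and GC content from its longest transcript per gene.

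The rule for named genes was also fixed before the data were examined. It took KAT7 and its complex partners, the 12 genes higher and 12 lower with the interval bound nearest 0 farthest from 0, and up to 4 members of each list. The genes needed a symbol of their own and at least 100 counts summed over both libraries, and mitochondrial genes and pseudogenes were left out. Not every gene that this rule takes is reported here. The named list members had the largest log2 ratios in size among those 1.5-fold or more different with an interval that excluded 0.

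The procedure was tested on simulated counts for this comparison over 13222 genes. All 100 genes given a true log2 ratio of 1.5 in size and all 100 given 2.5 were called in the right direction. Of 13022 unchanged genes, 1 was called higher and 4 lower, and 95.3% of their intervals included 0. Of 200 random lists of 20 unchanged genes, 5.5% lay outside the central 95%, and of 200 lists shifted by 0.3 on the log2 scale 100% lay above it. The simulation holds counting error and no variation between cultures.

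The alternatives were total-count scaling, size factors from DESeq2 1.42.0, a prior count of 5, other expression filters, fold thresholds and interval rules, the authors' folds, and other matching of the random lists. Total-count scaling moved log2 ratios by a median of -0.11, and DESeq2 size factors by -0.01. The move was smaller for RNVU1-7, which has 0 counts in siControl (8.39 to 8.33 under total-count scaling). The remaining computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.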

Results

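RNA-seq of HCT116 cells was compared between a culture transfected with an siRNA against KAT7 and a culture transfected with a non-specific siRNA. HCT116 is an epithelial cell line from a human colon carcinoma. KAT7, also called HBO1, is a lysine acetyltransferase of the MYST family that acetylates histones in complexes with JADE or BRPF scaffold proteins. The comparison asked how lowering KAT7 changes transcription in these cells. Each group had 1 library, and the named genes summed to 23450326 expected counts in siControl and 23533134 in siKAT7. No value below has a replicate, and the intervals cover counting error only. The exceptions are the intervals marked as bootstrap, which reflect the spread among genes and not between cultures.

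KAT7 was lower in siKAT7, at 69.6% of the siControl level (95% counting interval 59.7% to 80.8%). It had 442.94 expected counts in siControl and 287.22 in siKAT7, or 18.2 and 12.7 CPM. The log2 ratio was -0.52, with an interval of -0.74 to -0.31. None of the 9 measured partners of KAT7 in its complexes was 1.5-fold higher or lower, and their median log2 ratio was -0.02. The scaffold genes JADE1 and BRPF1 had log2 ratios of -0.10 (-0.33 to 0.12) and -0.02 (-0.18 to 0.13).

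KAT7 (ENSG00000136504) lies on chromosome 17 at 49788555 to 49835030 of GRCh38, on the forward strand. Among the 500 genes of nearest expression, 2.0% had a lower log2 ratio than KAT7, and the central 95% of them ran from -0.49 to 0.62. KAT7 has a long gene model, and of 466 long genes within 2-fold of its expression 3.43% had a lower ratio, which places KAT7 inside the central 95% of those. KAT7 ranked 763 from the lowest of 13217 genes, so its own decrease was smaller than that of many other genes. In the authors' deposited table KAT7 has a log2 fold of -0.63 and an adjusted p of 8.9e-08, and it was not marked significant there, because its fold is under the limit. Among the other partners, JADE2 had a log2 ratio of 0.06, JADE3 0.20, BRPF3 0.01, BRD1 -0.06, ING4 -0.29, ING5 -0.07 and MEAF6 0.07. Under total-count scaling JADE2, BRPF3 and MEAF6 turned negative, at -0.05, -0.10 and -0.04, and BRPF3 was -0.0043 with DESeq2 size factors. The interval of ING4 ran from -0.59 to 0.01.

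In siKAT7, integrated stress response and immediate early genes were higher and genes of DNA replication and the cell cycle were lower. The heat shock and NRF2 target lists lay within the range of random lists. Of the 13217 genes, 179 were at least 2-fold higher and 144 at least 2-fold lower. With total-count scaling the numbers were 130 and 188, and at a mean of at least 10 CPM they were 27 and 2. The balance between higher and lower genes thus depended on the scaling and on the expression filter. Of the genes passing the 2-fold rule, 92 of the higher ones and 107 of the lower ones were protein-coding. Counting intervals included a log2 ratio of 0 for 54.99% of all genes, against 95.3% of unchanged genes in the simulation, so the libraries differed by more than counting error. Without replicates these differences could not be set against the spread between cultures. Among the 2260 genes with a mean of 1 to 3 CPM, the central 95% of log2 ratios ran from -1.38 to 1.32. BIRC3, HRK, SP5, HIST2H4A, GPAM, CENPE, POLE2, HEY1, TNFRSF10C and IFI27, named below, had such expression and lay inside that range. CXCL3 lay at its upper end. IPP, RTN4IP1, TM4SF19, TMEM140, ZEB1-AS1 and STX16-NPEPL1, also named below, had such expression and lay beyond that range. The rule for named genes took these as extremes, so their place beyond it is no separate result.

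**Figure D1:**
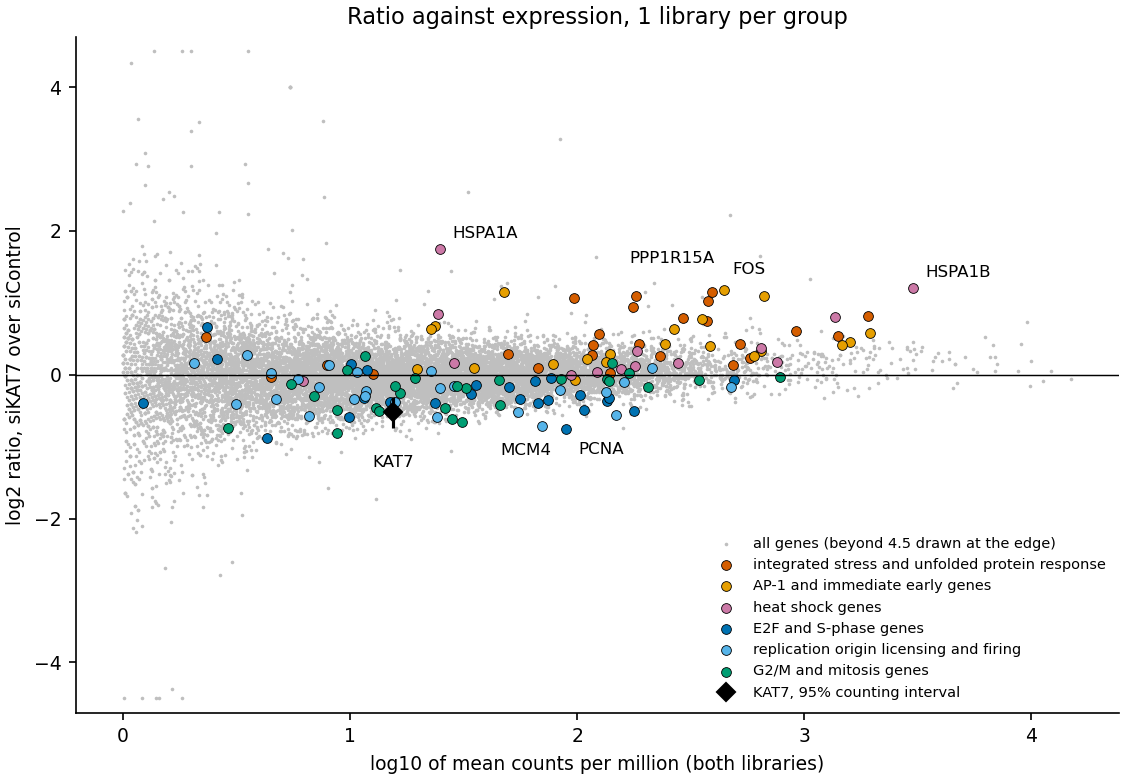
Each grey point is a gene, with the log10 of its mean CPM on the x axis and its log2 ratio, siKAT7 over siControl, on the y axis; coloured points are members of 6 gene lists and the diamond is KAT7 with its 95% counting interval. KAT7 sits at -0.52, HSPA1B at 1.21 and FOS at 1.18 lie above the cloud at high expression, and PCNA at -0.76 lies below it.

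The integrated stress and unfolded protein response list had the highest median of the 33 described lists. This list holds targets of the transcription factors ATF4, DDIT3 and XBP1, which act when protein folding or amino acid supply is disturbed. Of 25 measured members, 24 had a log2 ratio above 0, 9 were at least 1.5-fold higher and 0 were lower. PPP1R15A, which directs dephosphorylation of the translation factor eIF2-alpha, was 2.23-fold higher (log2 ratio 1.16, interval 1.11 to 1.20). TRIB3, a pseudokinase, CHAC1, which degrades glutathione, and the transcription factor DDIT3 (CHOP) were 2.13-fold, 2.09-fold and 2.04-fold higher. The list median was 0.43, above all of the random lists (percentile 100). Under total-count scaling the median was 0.33 and 8 members were at least 1.5-fold higher. PPP1R15A is on chromosome 19 and had 5954 counts in siControl and 12357 in siKAT7. DDIT3, on chromosome 12, had 6040.71 and 11459.98.

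Immediate early genes of the AP-1 and related families were also higher. FOS, FOSB and JUN, subunits of the AP-1 transcription factor, were 2.26-fold, 2.22-fold and 2.13-fold higher. ATF3, a related stress-induced factor, was 1.72-fold higher. Of 21 members, 20 had log2 ratios above 0, 7 were at least 1.5-fold higher and 0 lower, with a median of 0.41 at percentile 100. Under total-count scaling FOS, FOSB, JUN and ATF3 were the 4 members still 1.5-fold higher. JUN, on chromosome 1, had 10404 counts in siControl and 20656 in siKAT7, and FOS, on chromosome 14, had 6607 and 13907. In the MAPK feedback list the growth factor gene HBEGF was 1.59-fold higher, with a log2 ratio of 0.56 and under the 1.5-fold limit with total-count scaling, while the list median of 0.08 lay at percentile 71.8 and was -0.03 under total-count scaling.

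Heat shock and oxidative stress genes showed large ratios for a few members. HSPA1A and HSPA1B, which encode near-identical HSP70 chaperones on chromosome 6, had log2 ratios of 1.75 and 1.21. Reads of this pair can be divided between them, and their summed counts of 44610 in siControl and 96304 in siKAT7 gave 1.21 (1.20 to 1.23). The co-chaperones HSPH1 and DNAJB1 were 1.80-fold and 1.74-fold higher. Of 14 heat shock members, 4 were at least 1.5-fold higher and 0 lower, and the median of 0.17 lay within the random range at percentile 94.8. HMOX1, which encodes the haem-degrading enzyme haem oxygenase, was 3.10-fold higher, from 1442 to 4165 counts (log2 ratio 1.63, interval 1.55 to 1.72). OSGIN1, another NRF2 target, was 1.81-fold higher. The remaining 16 of the 18 NRF2 targets were not 1.5-fold different, and the list median of 0.12 lay at percentile 85.4.

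Genes of S phase and DNA replication were lower in siKAT7. PCNA, the sliding clamp of the replication fork, was 1.69-fold lower (log2 ratio -0.76, interval -0.85 to -0.67), with 2727 counts in siControl and 1502 in siKAT7. The primase subunit PRIM1 was 1.83-fold lower. In the E2F and S-phase list, 21 of 25 members had log2 ratios below 0, 2 were at least 1.5-fold lower, and 1, POLE2, was 1.58-fold higher on 44 and 65 counts, with an interval that included 0 under total-count scaling. Under that scaling 5 members, PCNA and PRIM1 among them, were at least 1.5-fold lower. The list median of -0.32 lay at percentile 0 of the random lists.

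Origin licensing and firing genes followed the same direction. MCM4, a subunit of the replicative helicase MCM2-7, was 1.64-fold lower (log2 ratio -0.71, interval -0.82 to -0.61), from 2129 to 1209 counts. MCM4 lies on chromosome 8 and PCNA on chromosome 20. Of 26 members, 19 had log2 ratios below 0, but 25 were less than 1.5-fold different or had intervals that included 0. With total-count scaling 5 members, MCM4 among them, were at least 1.5-fold lower. The median of -0.20 lay at percentile 0.080. Genes of G2 and mitosis had a median of -0.16 at percentile 0.27, with 23 of 27 members below 0 and 4 at least 1.5-fold lower. These were the kinetochore genes CENPF (1.75-fold lower) and CENPE (1.67-fold lower) and the cyclins CCNB2 (1.58-fold) and CCNA2 (1.53-fold). In the DNA repair list EXO1, an exonuclease gene, and RAD51AP1 were 1.75-fold and 1.80-fold lower. The other 24 measured repair genes did not pass, and the list median of -0.11 lay at percentile 10.2.

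**Figure D2:**
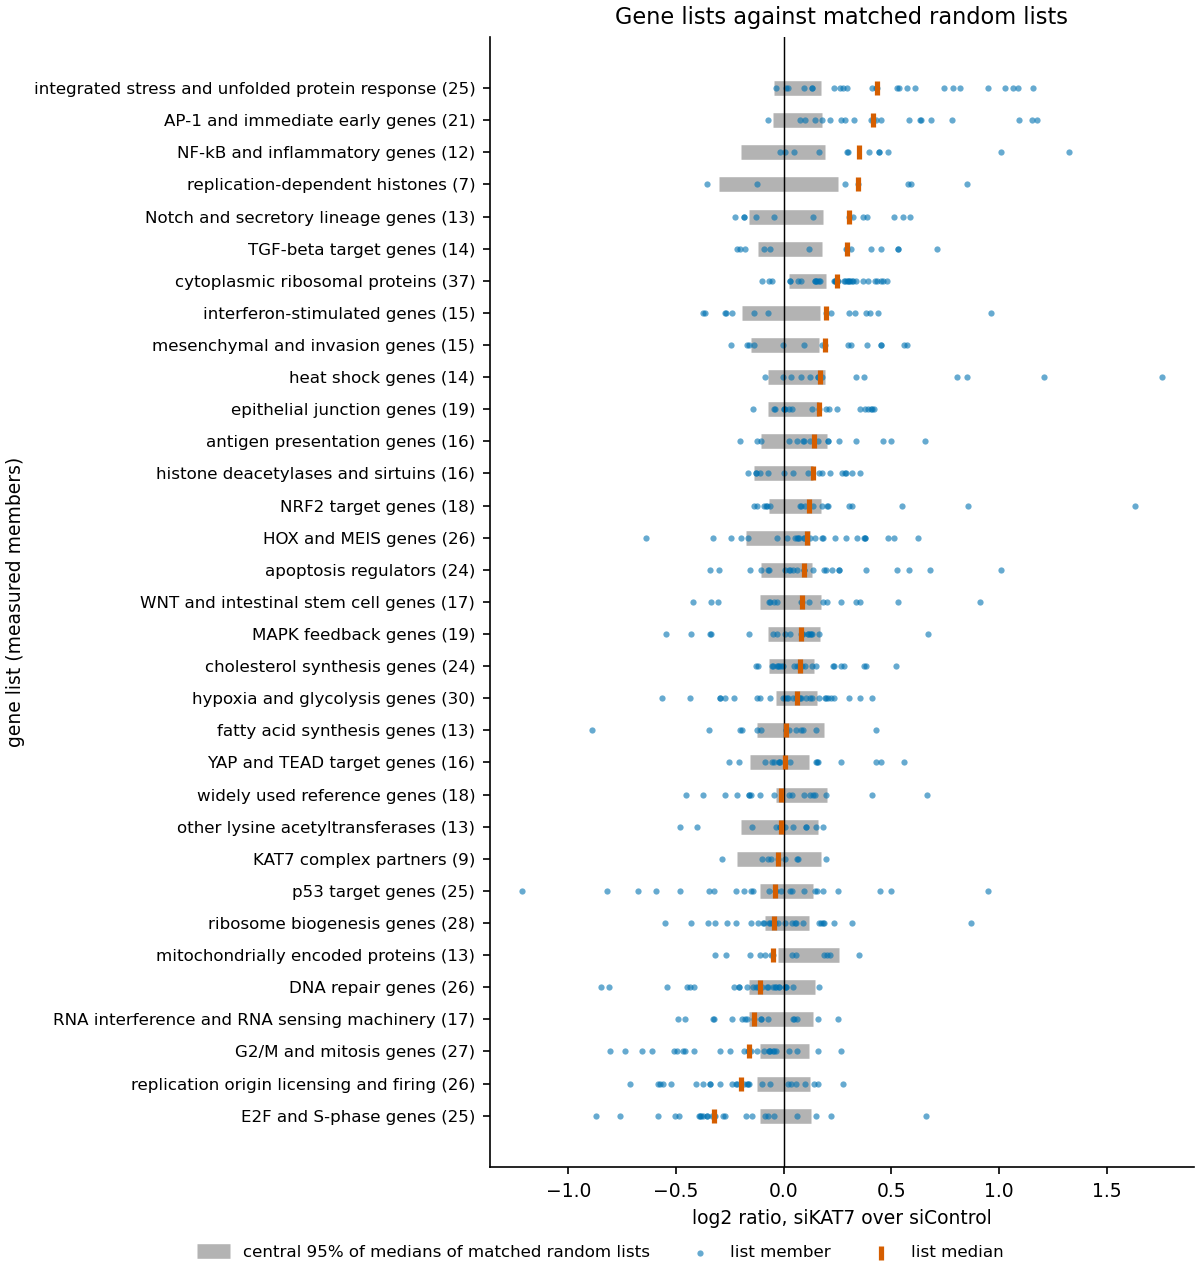
Each row is 1 of the 33 gene lists with at least 5 measured members; blue points are the members' log2 ratios, siKAT7 over siControl, the orange mark is the list median and the grey bar spans the central 95% of medians of 10000 expression-matched random lists. The stress list at 0.43 and the AP-1 list at 0.41 lie to the right of their bars, and the E2F list at -0.32 lies to the left.

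Targets of p53 moved both ways, with 10 of 25 measured members above 0 and 15 below. SESN2, which is also a target of ATF4, was 1.93-fold higher. TP53INP1, SESN1 and ZMAT3 were 1.77-fold, 1.60-fold and 1.51-fold lower. TNFRSF10C, a decoy receptor gene named after its values were seen, had a log2 ratio of -1.21 on 52.99 and 21.09 expected counts. Of 25 members, 1 was higher, 4 were lower and 20 did not pass, and the median of -0.04 lay at percentile 21.3. CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, had a log2 ratio of 0.04 (0.02 to 0.06) and was -0.07 under total-count scaling. Apoptosis regulators had a median of 0.09 at percentile 91.1, with BIRC3 2.01-fold and the BH3-only gene HRK 1.60-fold higher. These ratios rest on 43 and 81 counts for BIRC3 and 48 and 72 for HRK. Total-count scaling turned that median to -0.01 and put HRK under the 1.5-fold limit.

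Smaller positive medians stood apart for several signalling lists. Members of the NF-kB and inflammatory list had a median of 0.35 at percentile 99.97, with 11 of 12 above 0 and 2 at least 1.5-fold higher, BIRC3, an inhibitor of apoptosis, and the chemokine gene CXCL3 (log2 ratio 1.32). Among NF-kB genes with a mean of at least 10 CPM the median was 0.16, within the random range at percentile 94.4. TGF-beta targets had a median of 0.29 at percentile 99.95, with PMEPA1 1.64-fold higher and the other 13 members not passing. Notch and secretory lineage genes had a median of 0.30 at percentile 99.97, with the Notch effector HEY1 at a log2 ratio of 0.59 on a wide interval of 0.06 to 1.13, which included 0 under total-count scaling. HEY1 was under the 1.5-fold limit with that scaling and with DESeq2 size factors. Among Notch genes with a mean of at least 10 CPM the median was -0.05, at percentile 21.6. Mesenchymal and invasion genes had a median of 0.19 at percentile 98.97 with 0 of 15 members passing. Interferon-stimulated genes had a median of 0.20 at percentile 98.9, or 96.7 with length and GC content matched as well, with 8 members above 0, 7 below and 1 of 15, IFI27, at least 1.5-fold higher (log2 ratio 0.96). CXCL3 and IFI27 had fewer than 100 summed counts and were named after their values were seen.

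Among the chromatin and translation lists, the histone list had the largest median, and the others moved by 0.25 or less in size. Histone deacetylases and sirtuins had a median of 0.14 at percentile 97.8 with 0 of 16 members passing, and at percentile 86.9 with a mean of at least 10 CPM, 95.3 without matching and 97.4 with 5 bins, each within the random range, and the other lysine acetyltransferases had -0.01 at percentile 55.4 with 0 of 13. Only 7 of the 29 replication-dependent histone symbols passed the expression filter, so the list result covers those alone. Of the 7 measured histone genes, HIST2H4A and HIST1H2BD were 1.81-fold and 1.51-fold higher and 5 did not pass the 1.5-fold rule. Under total-count scaling HIST1H2BD had a log2 ratio of 0.49, and with either other scaling it was under the 1.5-fold limit. Their median was 0.34 at percentile 99.5, or 95.7, within the random range, with length and GC content matched as well. HIST2H4A had 39.21 and 66.47 expected counts, so part of its reads fitted other gene models and their division is uncertain. HIST1H2BD had whole counts of 224 and 315. Cytoplasmic ribosomal protein genes had a median of 0.25 at percentile 99.9, with 34 of 37 above 0 and 0 of them 1.5-fold higher. Mitochondrially encoded proteins had a median of -0.05 at percentile 0.93, against 0.10 in the matched random lists, and 0 of 13 were 1.5-fold different. That list lay within the random range without matching (percentile 32.05), with 5 bins (7.16) and with length and GC content matched (3.21).

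The remaining lists lay within the central 95% of the random lists. Epithelial junction genes had a median of 0.16 at percentile 97.4 and antigen presentation genes 0.14 at percentile 89.3, each with 0 members passing. HOX and MEIS genes had a median of 0.11 at percentile 96.5, with HOXA3 1.56-fold lower. Ribosome biogenesis genes had -0.05 at percentile 13.3, with UTP15, named after its values were seen, at 0.87, and RNA interference and RNA sensing genes -0.14 at percentile 4.92. WNT and intestinal stem cell genes (0.08), hypoxia and glycolysis genes (0.06), cholesterol synthesis genes (0.07), fatty acid synthesis genes (0.01) and YAP and TEAD targets (0.00) all turned negative under total-count scaling, and the YAP and TEAD median was -0.0056 with DESeq2 size factors. Members of these lists past 1.5-fold were the WNT-induced factor SP5, 1.88-fold higher, and GPAM, an enzyme of glycerolipid synthesis, 1.85-fold lower. In all, 10 lists lay above the central 95%, 4 below and 19 within it. Chance alone would place 1.65 of the 33 outside.

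Markers of other cell types were measured in small numbers. For 5 lists fewer than 5 members passed the expression filter. These were fibroblast markers (3 measured), blood cell markers (4), endothelial markers (1), keratinocyte and squamous markers (3) and colonocyte differentiation genes (4), and no median was taken for them. Of these, KRT10, a keratin gene named after its values were seen, was at least 1.5-fold higher, with a log2 ratio of 0.73. Widely used reference genes had a median of -0.01 (-0.12 under total-count scaling) at percentile 7.27, with 9 members above 0 and 9 below.

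The genes with the largest ratios beyond counting error in siKAT7 were mainly short structural RNAs and readthrough models. RNVU1-7, a variant U1 small nuclear RNA, had 0 expected counts in siControl and 161.1 in siKAT7. Reads of U1 copies can be divided among them, and the 11 U1 entries with counts, chosen after their values were seen, summed to 36 and 348, a log2 ratio of 3.36 (2.88 to 3.91). RN7SK, the RNA of the 7SK particle, was 5.53-fold higher and RMRP, the RNA of RNase MRP, was 4.04-fold higher. RMRP has a further entry under another identifier, and both summed gave 53 and 283 counts, a log2 ratio of 2.51 (2.09 to 2.97). The 5.8S rRNA copies RNA5-8SN2 and RNA5-8SN3 had identical counts of 14.66 and 231.61, and RNA5-8SN4 was 5.84-fold higher. Reads of such copies cannot be assigned to 1 locus, and the 5 entries of 5.8S rRNA with counts summed to 6901 and 11838, a log2 ratio of 0.88 (0.84 to 0.92). GADD45G, a stress-inducible gene, was 3.57-fold higher, from 83 to 277 counts, and HSPA1A and HMOX1, described above, were the other protein-coding genes of this set that are not readthrough models.

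Readthrough genes in this set share exons with their parent genes, and their ratios were not kept when the counts of the overlapping models were summed. RPL36A-HNRNPH2 had a log2 ratio of 3.28, but with RPL36A and HNRNPH2 added the ratio was 0.21 (0.18 to 0.24). RBM14-RBM4 and STX16-NPEPL1 had log2 ratios of 2.23 and 2.26, and the sums with their parent genes had 0.08 (0.01 to 0.16) and -0.03 (-0.15 to 0.10). P2RX5-TAX1BP3 had -1.58, and the sum with P2RX5 and TAX1BP3 had -0.05 (-0.15 to 0.06).

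The lower genes by the same rule were mostly protein-coding and of modest expression. FAM220A had the interval farthest from 0, at 3.30-fold lower (log2 ratio -1.72, interval -2.01 to -1.45), from 486.26 to 136.83 counts. UNC5D, a netrin receptor gene, was 3.86-fold lower on 129.82 and 30.87 counts. ZNF395 was 2.08-fold lower, DEPDC1B 2.32-fold, TMEM203 2.11-fold and IRGQ 1.85-fold. IPP, RTN4IP1, TM4SF19 and TMEM140 were 3.20-fold, 2.95-fold, 2.83-fold and 2.67-fold lower, each on fewer than 100 counts per library. The antisense RNA ZEB1-AS1 was 3.59-fold lower on 86 and 22 counts. Its whole counts give no sign that reads were divided with another gene model, but without a stated strand setting the strand of its reads is unknown. Expected counts of most of these genes, with DEPDC1B, IPP and ZEB1-AS1 as the exceptions, were not whole in at least 1 library, so part of their reads fitted other gene models.

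Short genes were higher than long genes in siKAT7, and rRNA took a larger share of the counts. Among protein-coding genes without ribosomal protein genes, the shortest decile had a median log2 ratio of 0.15 and the longest decile -0.07. Ribosomal RNA genes held 0.781% of the named counts in siControl (Wilson 95% interval 0.777% to 0.785%) and 1.21% in siKAT7 (1.21% to 1.22%). Mitochondrial genes held 7.11% and 6.40%, and protein-coding genes 96.3% and 95.5%. The cytoplasmic ribosomal protein list, which holds short and abundant transcripts, held 8.33% in siControl and 9.34% in siKAT7.

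**Figure D3:**
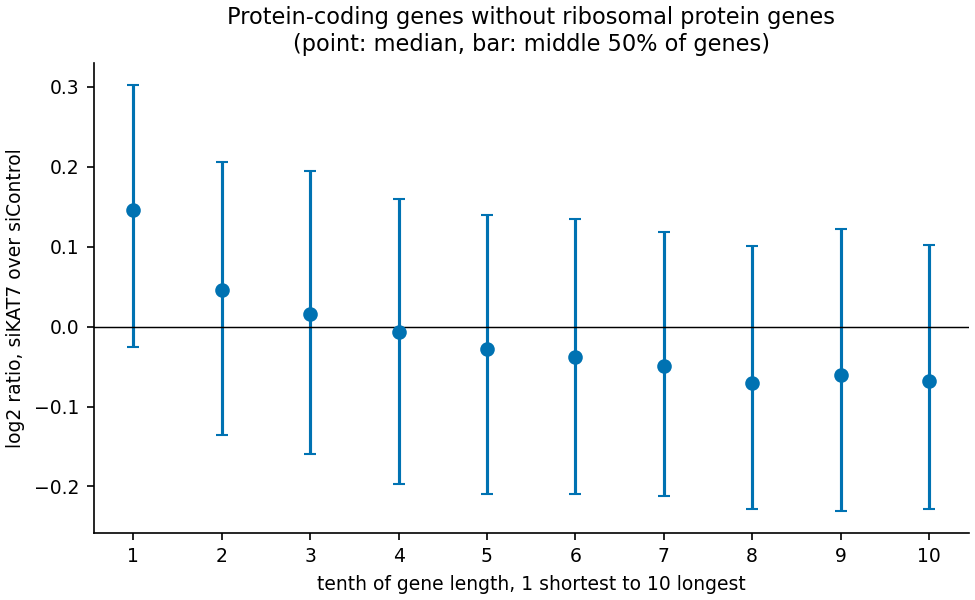
The x axis divides 11822 protein-coding genes without ribosomal protein genes into deciles of gene length, and the y axis gives the median log2 ratio, siKAT7 over siControl, with bars for the middle 50% of genes. The medians go from 0.15 in the shortest decile to -0.07 in the longest.

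The authors' deposited table marks 310 genes significant, 144 higher and 166 lower, and leaves 37113 of its 60623 genes untested. Across 13217 genes its log2 folds and the ratios given here had a Spearman rho of 0.999, a description across genes that are not independent replicates. Of the genes at least 2-fold different here, 86 of the 179 higher and 98 of the 144 lower were also marked in that direction in the authors' deposited table.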

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

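The matching on length and GC content and all tests of explanations below were chosen after the patterns were seen, and those of the stress and heat shock lists, the interferon response, p53 and CDKN1A, RNA length and the ribosomal protein list after the values they rest on were seen in part or in full. The percentiles with expression alone matched, those of p53 targets among them, were planned.

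Unnamed assembled loci, which no comparison used, held 1.67% of all counts in siKAT7 (Wilson 95% interval 1.66% to 1.67%) against 1.11% in siControl (1.10% to 1.11%). This signal lies in data outside the gene comparisons and above the level in the control library. The 4 largest of the 331 loci held 87.0% of it in siKAT7 and 84.1% in siControl.

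Integrated stress response and immediate early genes were higher in siKAT7, while NRF2 targets lay within the random range at percentile 85.4. Gene length, GC content and expression do not account for the integrated stress and AP-1 lists, which lay at percentile 100 both of random lists matched on all 3, in 5 bins each, and of lists matched on 20 bins of expression. For the heat shock list this stays undecided, since it lay at percentile 98.7 with the first matching and at 94.8, within the central 95%, with the second. Both cultures were transfected with siRNA, so an interferon response common to both would cancel in the ratio and could not be seen. A stronger interferon response to transfected RNA in siKAT7 stays undecided. The interferon-stimulated list lay at percentile 96.7 of lists matched on all 3, within the central 95%, and at 98.9 with expression alone matched. Only 15 of the 30 symbols of the interferon-stimulated list passed the expression filter, and IFIT1, MX1, RSAD2 and CXCL10 were not among them. Its percentile therefore covers the measured members alone. Of its 15 members 1 was higher, against 9 of 25 in the stress list, and its members moved both ways. Counting intervals lay above 0 for IFI27, ISG20, ISG15, OASL, IFI6 and IRF7 (log2 ratios 0.96, 0.40, 0.38, 0.33, 0.30 and 0.20) and below 0 for OAS3, USP18 and STAT2 (-0.37, -0.37 and -0.27), all named after their values were seen. That the lower KAT7 level raised the stress genes remains a hypothesis, untested, with KAT7 still at 69.6% of its siControl level. A difference in handling or transfection stress between the cultures stays as open with 1 library each. So do effects of the KAT7 siRNA on other genes, which could not be told apart from effects of the lower KAT7 level.

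Replication and cell cycle genes were lower in siKAT7. Gene length, GC content and expression do not account for it, since the highest of the percentiles of the licensing, E2F and G2/M lists was 0.825 among lists matched on all 3. For these 2 libraries a p53 response with higher CDKN1A is argued against. The highest upper bound of the CDKN1A log2 ratio under 3 scalings was 0.062, and p53 targets lay within the random range. That bound covers counting error only, so it cannot exclude such a response in other cultures. A slower cycle at the lower KAT7 level, an effect of KAT7 on these genes, or a difference in cell density between the cultures stay open. All are hypotheses, untested here, and the decrease of KAT7 was partial. Effects of the siRNA on other genes could not be told apart from effects of the lower KAT7 level. No other KAT7 siRNA treatment was sequenced.

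Short RNAs and rRNA were higher in siKAT7. Shorter or less intact RNA in 1 library predicts a trend over all transcripts, and the shortest decile of protein-coding genes exceeded the longest by 0.17 (bootstrap interval 0.13 to 0.20) with expression held in bins. That value is consistent with a difference in fragment or RNA length between the libraries. Whether gene length, GC content and expression account for the higher ribosomal protein list stays undecided. Its median of 0.25 lay at percentile 99.92 both among lists matched on all 3 and among lists drawn from the 50 nearest protein-coding genes of each member that encode no ribosomal protein, but those genes had a median of 749 CPM against 1926 for the members. Among genes in the shortest quintile with at least 1000 CPM, 25 members exceeded 34 other genes by 0.13 (bootstrap interval 0.04 to 0.23), at median lengths of 709 and 902 nt. A fit on the 3 properties over other genes of at least 100 CPM left 0.051 (-0.014 to 0.17) of the members' median, and over those of at least 300 CPM it left 0.13 (0.04 to 0.21). A difference in how much rRNA and small RNA the library preparation left, and a biological difference between the groups, stay open and were not tested.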

How the results depend on the processing

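KAT7 stayed lower, with an interval below 0, under each alternative run, including the adjustment for length, GC content and expression. That adjustment, the restriction to protein-coding genes and the matching of random lists on length and GC content were chosen after seeing the data. Deposited TPM or FPKM values and separate columns per library were not run, because the files used here held no such values and the repeated columns were identical. No paired analysis was possible because each group has 1 library. Of 230 gene list medians under alternatives, 221 kept their sign and 217 their side of the central 95% of random lists. Of 214 values of named genes, 210 kept their sign. The other 4 were those of JADE2 and MEAF6 under total-count scaling and of BRPF3 under that scaling and DESeq2 size factors. Most named genes were taken for ratios far from 0, so shifts of this size could not turn their sign.

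The 179 higher and 144 lower genes became 668 and 607 without a filter on low counts, 27 and 2 at a mean of at least 10 CPM, 60 and 22 with the whole interval beyond 2-fold, and 518 and 517 at 1.5-fold. Protein-coding genes gave 92 higher. The CPM filters change which genes are counted, and the fold and interval settings change the cut on the same genes. Low counts limit most of the 2-fold genes, since few reach 10 CPM.

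At 10 CPM, where fewer members are measured, the Notch median turned to -0.047, and those of the deacetylases (0.078) and NF-kB list (0.16) lay within the random range. Medians do not change with the matching, only their percentiles. The deacetylases (0.14) lay within the range for unmatched lists and for 5 bins. The junction genes (0.16) lay above it for the same settings. Mitochondrial proteins (-0.050) lay within it for unmatched lists, for 5 bins and with length and GC content matched. With length and GC content matched, the interferon genes (0.20) and histones (0.34) lay within it and the heat shock genes (0.17) lay above it. Total-count scaling moved every list median by about -0.11 by construction and left each list on its side of the random range. This brought hypoxia genes to -0.043, cholesterol genes to -0.034 and ribosome biogenesis genes to -0.15. For the changes with matching, the cause was not tested.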

Other observations

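Biological process terms of the deposited annotation were examined after seeing the data, 1361 terms of 15 to 200 measured genes, against random lists matched on length, GC content and expression. Of these, 137 lay outside the central 95%, where chance gives 68.1. Genes of purine nucleotide synthesis, which the fixed lists did not cover, were lower in siKAT7, with a median log2 ratio of -0.30 over 19 genes (percentile 0.010), 15 of them below 0. PFAS, ATIC and PAICS, enzymes of the de novo pathway, had -0.48 (-0.63 to -0.34), -0.47 (-0.69 to -0.26) and -0.39 (-0.50 to -0.29). The salvage enzyme gene HPRT1 had -0.45 (-0.58 to -0.32), while IMPDH2 had 0.02 (-0.0046 to 0.05), which is -0.09 under total-count scaling. None of the 19 genes was 1.5-fold different.

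Genes of the tricarboxylic acid cycle were lower as well, with a median of -0.20 over 37 genes (percentile 0.010) and 29 of them below 0. Of the 37, 2, DLD and the pseudogene SDHAP2, were at least 1.5-fold lower and 1, a clone with no symbol of its own, was higher. The term holds some pseudogenes and unnamed clones beside the enzymes. DLD, a subunit shared by mitochondrial dehydrogenase complexes, had -0.71 (-0.97 to -0.45), and PDHA1 and SDHD, subunits of pyruvate dehydrogenase and of succinate dehydrogenase, had -0.49 (-0.61 to -0.38) and -0.48 (-0.59 to -0.38). CS and IDH2 were near 0, at 0.00 and 0.01, and at -0.11 and -0.09 under total-count scaling. At the other end lay protein targeting to the membrane by the signal recognition particle, with a median of 0.23 over 89 genes, of which 68 encode ribosomal proteins. These genes were named after their values were seen.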
